A study of Saccharomyces cerevisiae BY4741 with 22 samples.

How the data were processed

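The data were 22 libraries of 3' end sequencing (3'-RACE) of ribosomal RNA from the yeast Saccharomyces cerevisiae, 18 of 18S rRNA and 4 of 25S rRNA. Per the labels' protocols, 18S rRNA came from purified small subunits and 25S rRNA from large subunits. A DNA linker was ligated to the RNA 3' end, and the fragment between an rRNA-specific primer and the linker was amplified and sequenced. The deposited values are whole-number read counts per nucleotide, that is, the depth of reads at each of 6858 positions of the 35S precursor, per the file headers. The submitters' processing notes name Trim Galore 0.6.1, cutadapt 3.5, FastQC 0.11.4, Bowtie2 2.2.9, SAMtools 1.1.0, bedtools 2.17.0 and UMI-tools 1.1.2. Their settings, and whether duplicate reads were removed by molecular identifier (UMI), are not given in the sources used here. Every column was matched to its sample by the title in the file header.

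The RefSeq gene table of assembly R64 places mature 18S rRNA at positions 701 to 2500 of the 35S precursor and 25S rRNA at 3252 to 6647. The most frequent 3' end fell on position 2500 in 18 of 18 libraries of 18S and on 6647 in 4 of 4 libraries of 25S. This position is called 0, negative numbers lie inside the mature rRNA (truncated ends) and positive numbers beyond it (extended ends). No genome coordinate is given because the files name no genome build.

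Ends were derived from the depth as lasting drops: a drop that was made up again further 3' was taken as a skipped nucleotide, not as an end. The rule fixed before the data were examined was different. It set negative drops of depth to 0 and counted each positive drop as an end. The lasting drop was chosen after the depth profiles had been seen and before any groups were compared, because reads skip nucleotides inside 18S rRNA. Under the earlier rule those skips count as truncated ends, and the truncated share of the Rps14 + Dim1 libraries becomes 10.7% ± 1.02 (SD, n = 2) in place of 0.886% ± 0.149 (SD, n = 2). The change of rule also changes whether the main 18S comparison passes its test, so the results under both rules are printed beside each other. The alternative fixed together with the earlier rule, negative drops kept in the sum from the position of highest depth, was also run. Its truncated count equals that of lasting drops by construction, so it is no separate check of them. Upstream of the position of highest depth no end can be seen, so truncated ends were counted from about -18 onwards. From there on, an end hidden behind a later rise in depth is counted at a position further upstream.

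Shares were computed over ends within 50 nt of position 0, as ends other than position 0 (miscleaved), upstream of it (truncated) or downstream of it (extended). They were compared as log2 odds against the ends at position 0, with 0.5 added to both counts. Each library held between 2562767 and 4373681 ends in this window. The widest 95% Wilson interval of any library's share reached 0.0245 percentage points to either side. Reads copied by PCR are not independent molecules, so intervals and floors (3 ends) cover counting error only. The labels call the libraries biological replicates.

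The 16 libraries of Pno1 and Pno1-KKKF 18S rRNA were made under 3 protocols, which are named here by temperature and linker. Per strain, 3 libraries came from cultures at 30 °C with the universal linker, 2 from 25 °C with the universal linker, and 3 from 25 °C with a linker holding a UMI. Universal-linker libraries were purified on gels and UMI libraries on beads. Strain labels were therefore exchanged only within a protocol, in a two-sided exact permutation test of 2400 arrangements, with Benjamini-Hochberg adjustment over the 3 shares. The 25S libraries all followed the 30 °C universal protocol, and the Rps14 + Dim1 libraries the 25 °C UMI protocol, and each was compared within that protocol. Region groups, adjusted over 8 groups, were fixed before the data were examined.

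Ends per position were tested with edgeR 4.0.16 (R 4.3.3), by its quasi-likelihood test with the total ends as library size and Benjamini-Hochberg adjustment at 0.05. Positions needed at least 10 ends in at least 3 libraries (2 libraries for 25S and for Rps14 + Dim1), and protocol was a term for the 16 libraries. DESeq2 1.42.0 was an alternative. Other steps used Python 3.11.15 with numpy 2.4.6 and scipy 1.17.1. Positions named were fixed by rule: 0, -3 to +5, -10 and +10, the 5 most frequent other ends per group, and up to 10 positions per direction with the smallest p past the threshold. Where none passed, the 3 with the smallest p were named. Other positions named below were chosen after their values were seen.

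The derivation was tested on simulated data. In 20 simulated depth profiles with skipped nucleotides, lasting drops returned the ends with an error of 0, while setting negative drops to 0 gave up to 15.2% truncated ends where the truth was 1.65%. No simulated end lay on or next to a skipped nucleotide, so the error of 0 was set by the design and says nothing about ends there. The permutation test gave p under 0.05 in 4.5% of 400 simulations without an effect. For the Pno1-KKKF 18S comparison (46 positions), the edgeR test found 8.47% of simulated 1.5-fold changes, 51.8% of 2-fold changes and 98.3% of 4-fold changes. For 25S (19 positions) it found 55.0% of 4-fold changes, and for Rps14 + Dim1 (45 positions) 62.7%. Alternatives covered the window, the scale, the exchange of labels, replicate blocks, single protocols, single libraries left out, thinning to equal depth, normalization, filter and tool. No pair of replicate libraries was a duplicate: over 59 pairs, the lowest chi-square per degree of freedom was 5.54.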

Results

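The series measured where 18S rRNA ends in yeast cells that make their small ribosomal subunits with altered assembly factors. The cells were depleted of their own Pno1 and Dim1, or of Rps14 and Dim1, and carried plasmid copies. Pno1 is an assembly factor that binds near the 3' end of 18S rRNA, and Dim1 is the methyltransferase that modifies adenosines close to that end. The 18S libraries comprised 8 of Pno1 with Dim1-E85A, 8 of the mutant Pno1-KKKF with Dim1-E85A and 2 of Rps14 with Dim1. The 25S libraries comprised 2 of each Pno1 strain. The ends counted per library numbered 2615354 to 2847541 in the 6 18S libraries from 30 °C with the universal linker. They numbered 2928262 to 4373681 in the 4 from 25 °C with that linker, 2720964 to 3518259 in the 8 with the UMI linker, and 2562767 to 2845589 in the 4 25S libraries. Mature 18S rRNA has 1800 nucleotides and ends at position 2500 of the 35S precursor, called position 0 here.

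In every group nearly all 18S rRNA ended at position 0. The share of ends there was 98.2% ± 0.883 (SD, n = 8) in Pno1, 97.5% ± 1.25 (SD, n = 8) in Pno1-KKKF and 99.1% ± 0.150 (SD, n = 2) in Rps14 + Dim1. The most frequent other end in all 3 groups was at -4, with 0.743% ± 0.426 (SD, n = 8) of ends in Pno1, 1.13% ± 0.708 (SD, n = 8) in Pno1-KKKF and 0.345% ± 0.0600 (SD, n = 2) in Rps14 + Dim1. It was followed by -1 and -9 in each group, then by -8 and -7 in Pno1 and Rps14 + Dim1 and by -7 and -8 in Pno1-KKKF. For Pno1 and Pno1-KKKF these ranks are of means over the protocols. Rps14 + Dim1 was sequenced in UMI libraries only. Within the UMI libraries, ends at -4 made up 0.362% ± 0.104 in Pno1 and 0.441% ± 0.0772 in Pno1-KKKF, and ends at -1 made up 0.350% ± 0.0676 and 0.440% ± 0.0263 (SD, n = 3 each), against 0.315% ± 0.0138 at -1 in Rps14 + Dim1 (SD, n = 2). On 25S rRNA the most frequent other end was at -1 in both strains, with 2.35% ± 0.230 (SD, n = 2) in Pno1 and 2.23% ± 0.297 (SD, n = 2) in Pno1-KKKF, followed by +1 and +2.

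The first comparison asked whether cells with Pno1-KKKF, which the series describes as bypassing quality control of ribosome assembly, carry more 18S rRNA with a misplaced 3' end. Truncated 18S ends made up 1.65% ± 0.772 (SD, n = 8) of ends in Pno1 and 2.35% ± 1.20 (SD, n = 8) in Pno1-KKKF. Within protocol their odds were 1.41-fold higher in Pno1-KKKF (log2 difference 0.49, SE 0.20), and higher in 7 of 8 same-numbered libraries. Same-numbered libraries were not found to belong together, so this and later counts of pairs only describe the libraries and are no further test. All miscleaved ends together made up 1.80% ± 0.883 (SD, n = 8) and 2.50% ± 1.25 (SD, n = 8), a 1.38-fold difference in odds (log2 difference 0.47, SE 0.20). Extended ends made up 0.147% ± 0.121 (SD, n = 8) and 0.151% ± 0.0810 (SD, n = 8).

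Both shares were higher in Pno1-KKKF under either rule for ends, but whether the differences passed the test depended on the rule. With negative drops set to 0, truncated ends made up 2.86% ± 0.819 in Pno1 and 3.53% ± 1.22 in Pno1-KKKF (SD, n = 8 each). These shares were higher in both strains than with lasting drops. With lasting drops, the exact permutation test gave p = 0.0217 for truncated and p = 0.03 for miscleaved ends, both 0.045 after Benjamini-Hochberg adjustment over the 3 shares. With the rule fixed before the data were examined, negative drops set to 0, the truncated difference was 0.29 on the log2 scale (1.22-fold, SE 0.13) and the adjusted exact permutation p was 0.075 for both shares. Lasting drops were chosen after the depth profiles were seen, so the difference did not pass the test as first planned. Over the 12 alternatives other than single libraries, the adjusted exact permutation p ranged from 0.0437 to 0.6. The top of that range came from runs of single protocols, which hold too few libraries to pass. Labels exchanged over all 16 libraries gave an adjusted exact permutation p of 0.328. Negative drops kept in the sum, which kept the call, gives the truncated count of lasting drops by construction. Leaving out a single library ended the call in 12 of 16 cases, those of Pno1 replicates 2 to 6 and Pno1-KKKF replicates 1 to 4 and 6 to 8, with truncated log2 differences of 0.34 to 0.52 and adjusted exact permutation p of 0.05 to 0.116. Without Pno1 replicate 1, 7 or 8 or Pno1-KKKF replicate 5 the call stayed, with 0.54 to 0.59 and adjusted exact permutation p from 0.0025. The difference in the extended share did not pass under either rule (log2 difference 0.17, SE 0.26, exact permutation p = 0.498, adjusted p = 0.498, with lasting drops). By protocol it was -0.0029 at 30 °C (SE 0.47), 0.21 at 25 °C with the universal linker (SE 0.83) and 0.32 in UMI libraries (SE 0.11). The UMI value, higher in 3 of 3 pairs, had the smallest possible exact permutation p, 0.1. Without Pno1 replicate 1 the difference over all protocols was 0.33 (adjusted exact permutation p = 0.157).

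Within the protocols the truncated odds were 1.27-fold higher in Pno1-KKKF at 30 °C with the universal linker (log2 difference 0.35, SE 0.30), higher in 2 of 3 pairs. They were 1.89-fold higher at 25 °C with the universal linker (log2 difference 0.92, SE 0.60, 2 of 2 pairs) and 1.27-fold higher with the UMI linker (log2 difference 0.35, SE 0.26, 3 of 3 pairs). No protocol alone can reach p under 0.05, since the smallest exact permutation p is 0.1 for 3 libraries against 3 and 0.333 for 2 against 2. The highest truncated share of any library, 4.61%, was that of Pno1-KKKF replicate 4, and without it the log2 difference was 0.34 with an adjusted exact permutation p of 0.0912.

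**Figure D1:**
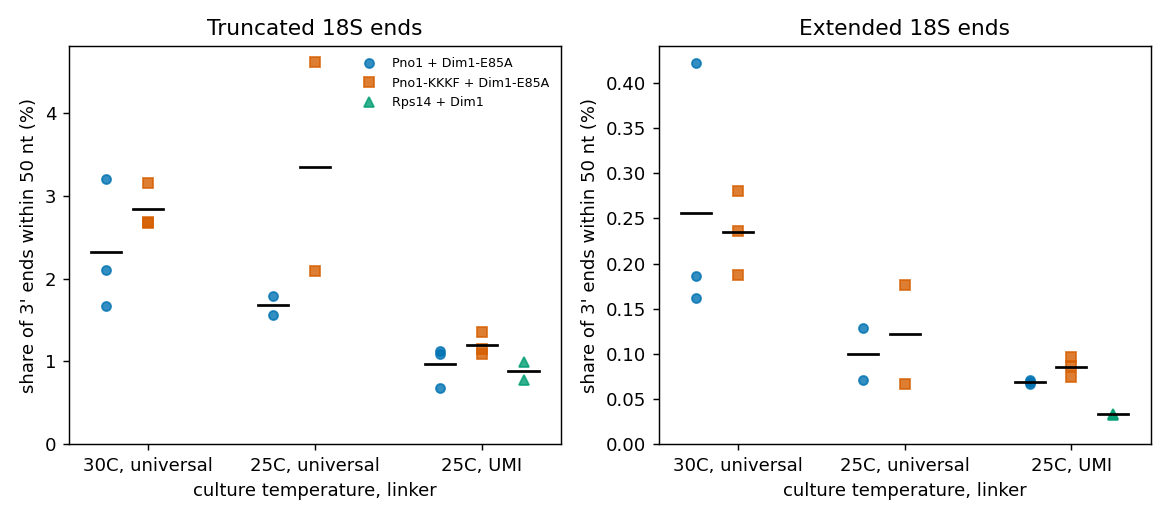
Share of truncated (left) and extended (right) 18S 3' ends among ends within 50 nt of position 0, in percent, by culture temperature and linker; each point is a library and each bar a mean. Truncated ends ranged from 0.678% to 3.20% in Pno1 and from 1.09% to 4.61% in Pno1-KKKF, and were least frequent in the UMI libraries of both strains.

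By region, ends at -10 to -3 made up 1.24% ± 0.710 (SD, n = 8) in Pno1 and 1.88% ± 1.21 (SD, n = 8) in Pno1-KKKF, 1.46-fold higher odds within protocol and higher in 6 of 8 pairs. Ends at -2 and -1 made up 0.386% ± 0.0608 (SD, n = 8) and 0.446% ± 0.0576 (SD, n = 8), 1.17-fold higher odds and higher in 6 of 8 pairs. Neither passed adjustment over the 8 groups (exact permutation p = 0.0317 and 0.045, adjusted p = 0.18 for both). Of the 8 groups, 0 passed, and 2 had an unadjusted exact permutation p under 0.05. The 8 include a short region at the A2 cleavage site of the precursor, starting at +200, which could be seen in UMI libraries alone. Ends there amounted to 0.00113% ± 0.000128 in Pno1 and 0.00176% ± 0.000419 in Pno1-KKKF (SD, n = 3 each), higher in 3 of 3 pairs, at the smallest exact permutation p the design allows, 0.1. All ends beyond +50, also seen in UMI libraries alone, had 0.892-fold odds in Pno1-KKKF and were higher in 1 of 3 pairs (exact permutation p = 0.7). How far the length of the reads limits ends beyond +50 is not known from the labels.

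Per position, the edgeR quasi-likelihood test called 0 of 47 positions between Pno1-KKKF and Pno1, with 6 positions at an unadjusted p under 0.05. DESeq2 called 0 with size factors from total ends (7 at an unadjusted p under 0.05) and 1 with its default size factors (11), position +22. Within single protocols edgeR called 10 positions at 30 °C with the universal linker, all lower in Pno1-KKKF and between +14 and +27. It called 2 at 25 °C with the universal linker, -9 and -4, both higher, and 6 in the UMI libraries, all higher and between +15 and +27. The calls at -9 and -4 rest on 2 libraries against 2. In these, ends at -10 to -3 ranged from 1.74% to 4.18% in Pno1-KKKF and from 1.19% to 1.40% in Pno1. With negative drops set to 0, edgeR called 1 of 64 positions, -20, where skips of the next nucleotide then count as ends. The 3 positions with the smallest p were -4, +22 and -2, each at an adjusted p of 0.312 in edgeR. Ends at -4 were 1.46-fold as frequent in Pno1-KKKF (log2 difference 0.54, SE 0.20) and higher in 7 of 8 pairs. Ends at -2 had a log2 difference of 0.47 (SE 0.19) and ends at +22 one of -0.97 (SE 0.36). Of the other frequent ends, -9, -7, -8 and -1 had log2 differences of 0.61, 0.54, 0.34 and 0.17. Position -10 had 0.61, -3 had 0.25 and position 0 had -0.01. Downstream, +1 to +5 had log2 differences of 0.00, 0.25, -0.20, 0.26 and 0.06, and +10 had 0.03.

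The 25S libraries served as the control for an effect limited to 18S rRNA. Miscleaved 25S ends made up 3.46% ± 0.306 (SD, n = 2) in Pno1 and 3.31% ± 0.341 (SD, n = 2) in Pno1-KKKF, a log2 difference in odds of -0.07 (SE 0.14). The exact permutation p was 0.667, where 2 libraries against 2 allow no p below 0.333. The sign turned without Pno1 25S replicate 2 (0.024) or Pno1-KKKF 25S replicate 1 (0.040). Truncated 25S ends made up 2.63% ± 0.244 and 2.49% ± 0.351, and extended 25S ends 0.836% ± 0.0620 and 0.820% ± 0.00981 (SD, n = 2 each). The edgeR test called 0 of 20 positions of 25S, with 2 at an unadjusted p under 0.05, and DESeq2 called 0 with size factors from total ends (3 unadjusted) and with its default size factors (2 unadjusted). Position -1 had a log2 difference of -0.08, 0 had 0.00 and +1 had -0.06. Positions -3, -2, +2, +3 and +4 had 0.10, -0.01, 0.35, 0.26 and -0.26, none of them passing. The 3 positions with the smallest p were +7, +6 and +5, with log2 differences of -1.28 (SE 0.26), -0.78 (SE 0.19) and -0.57 (SE 0.21) and edgeR adjusted p of 0.163, 0.163 and 0.345.

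Within the shared 30 °C universal protocol, the log2 difference of miscleaved odds between the strains was 0.32 on 18S and -0.07 on 25S. The difference of 0.38 between these effects did not pass the exact permutation test (p = 0.267, 120 arrangements). Single libraries moved this difference, to 0.67 without Pno1 18S replicate 1 (exact permutation p = 0.05) and to 0.17 without Pno1 18S replicate 3 (exact permutation p = 0.583).

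Rps14 + Dim1 cells, in which Dim1 is unmutated, were the control for the contribution of Dim1-E85A. They differ from the other strains also in the second protein that was depleted and replaced. All comparisons with them used UMI libraries. Miscleaved 18S ends made up 0.919% ± 0.150 (SD, n = 2) in Rps14 + Dim1, 1.03% ± 0.247 (SD, n = 3) in Pno1 and 1.29% ± 0.141 (SD, n = 3) in Pno1-KKKF. Against Pno1 the log2 difference in odds was -0.15 (SE 0.31, exact permutation p = 0.6), and against Pno1-KKKF it was -0.49 (SE 0.17, exact permutation p = 0.1). The smallest p that 2 libraries against 3 allow is 0.1. Truncated ends made up 0.886% ± 0.149, 0.964% ± 0.249 and 1.20% ± 0.138 in the same order. The difference from Pno1 turned to 0.021 without Rps14 + Dim1 replicate 1. With negative drops set to 0, the rule fixed beforehand, both differences changed sign, to 2.46 and 2.28, because skipped nucleotides then count as ends. At 18S nucleotide 1779, reads of Rps14 + Dim1 skipped the nucleotide in 10.9% ± 1.09 (SD, n = 2), those of Pno1 in 0.995% ± 0.559 and those of Pno1-KKKF in 1.00% ± 0.160 (SD, n = 3 each).

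**Figure D2:**
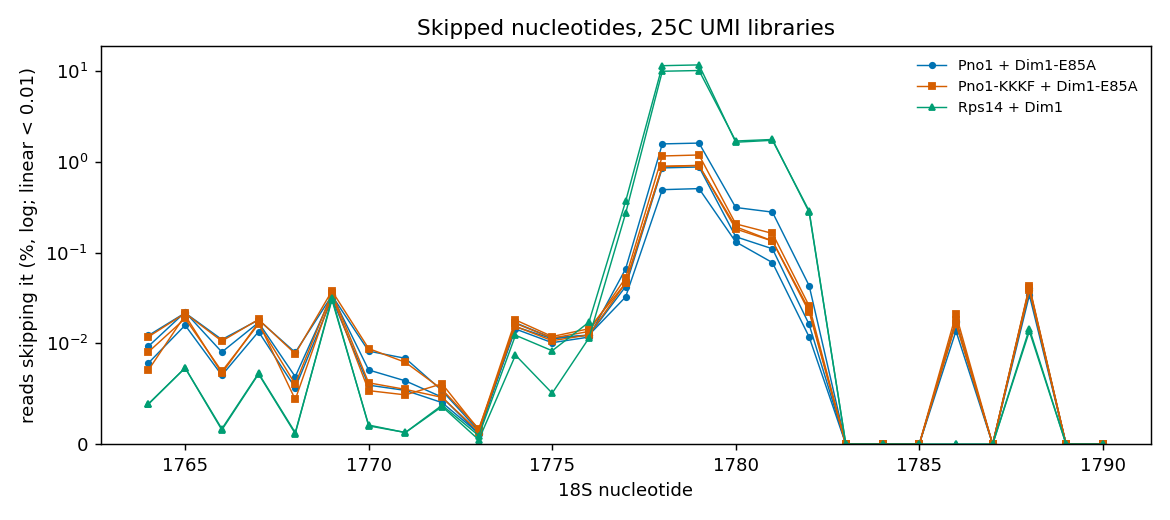
Share of reads that skip a nucleotide, in percent, against the nucleotide of 18S rRNA, for the 8 UMI libraries from 25 °C; each line is a library, and the vertical axis is logarithmic above 0.01 and linear below. At nucleotides 1778 and 1779 both Rps14 + Dim1 libraries lie above the 6 Dim1-E85A libraries.

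Extended 18S ends were less frequent in both Rps14 + Dim1 libraries than in any of the 6 Dim1-E85A UMI libraries. They made up 0.0333% ± 0.000763 (SD, n = 2) in Rps14 + Dim1, 0.0686% ± 0.00198 (SD, n = 3) in Pno1 and 0.0859% ± 0.0112 (SD, n = 3) in Pno1-KKKF. Their odds were 0.485-fold those of Pno1 (log2 difference -1.04, SE 0.03), again at the smallest exact permutation p of 0.1. Ends at +11 to +50 amounted to 0.00221% ± 0.000716 in Rps14 + Dim1 (SD, n = 2), 0.0246% ± 0.00561 in Pno1 and 0.0408% ± 0.00803 in Pno1-KKKF (SD, n = 3 each). The odds in Pno1 were 11.2-fold those in Rps14 + Dim1, at the smallest exact permutation p of 0.1.

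Per position, edgeR called 26 of 46 positions between Rps14 + Dim1 and Pno1, 25 of them lower in Rps14 + Dim1 and 1 higher. TMM normalization left 16, of which 15 were lower, and DESeq2 with its default size factors called 23, of which 14 were lower and 9 higher. Both scalings moved all positions up together, position 0 itself from 0.00 to 0.60 and 0.65 on the log2 scale, so the higher calls of DESeq2 do not give a direction relative to position 0. Without Pno1 replicate 8 the count was 15. The 10 lower positions with the smallest p were +25, +9, +18, +16, +27, +28, +32, +13, +17 and +12. Position +9 was 0.243-fold and +13 0.315-fold as frequent in Rps14 + Dim1, with edgeR adjusted p of 0.00486 for both, and +12 was 0.208-fold (adjusted p = 0.00732). Position +25 held 418 ends over the 3 Pno1 libraries and 2 over both Rps14 + Dim1 libraries. Position +18 held 95 and 1, +16 held 40 and 3, +27 held 92 and 2, +28 held 41 and 1, +17 held 53 and 1. Position +32 held 29 and 0, at least 3.20-fold lower against a floor of 3 ends per library.

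The 1 position called higher was -14, with 87 ends in Rps14 + Dim1 and 0 in Pno1. That 0 is no measurement, because reads of the Dim1-E85A UMI libraries skipped that nucleotide at 0.0137% to 0.0208%. Ends that fall together with such a dip are counted at -15 instead. The share of ends there was 0.00133% ± 0.000337 in Rps14 + Dim1 (SD, n = 2), with skips at 0%, so no fold is given. The frequent ends at -4, -1, -9, -8 and -7 had log2 differences of -0.07, -0.15, -0.17, 0.25 and -0.22 and did not pass. Positions -3, -2 and -10 had -0.69, -0.32 and -0.04 and position 0 had 0.00, none of them passing. Positions +3, +4 and +5 were lower in Rps14 + Dim1 (log2 differences -0.96, -0.76 and -0.87, edgeR adjusted p = 0.0222, 0.0365 and 0.0345), as was +10 (-1.21, adjusted p = 0.0286). Positions +1 and +2 had -0.12 and -0.31 and did not pass. With DESeq2's default size factors -1 and +1 had 0.52 and 0.54 and passed (adjusted p = 0.00785 and 0.0263), both below the 0.65 of position 0 under that scaling.

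**Figure D3:**
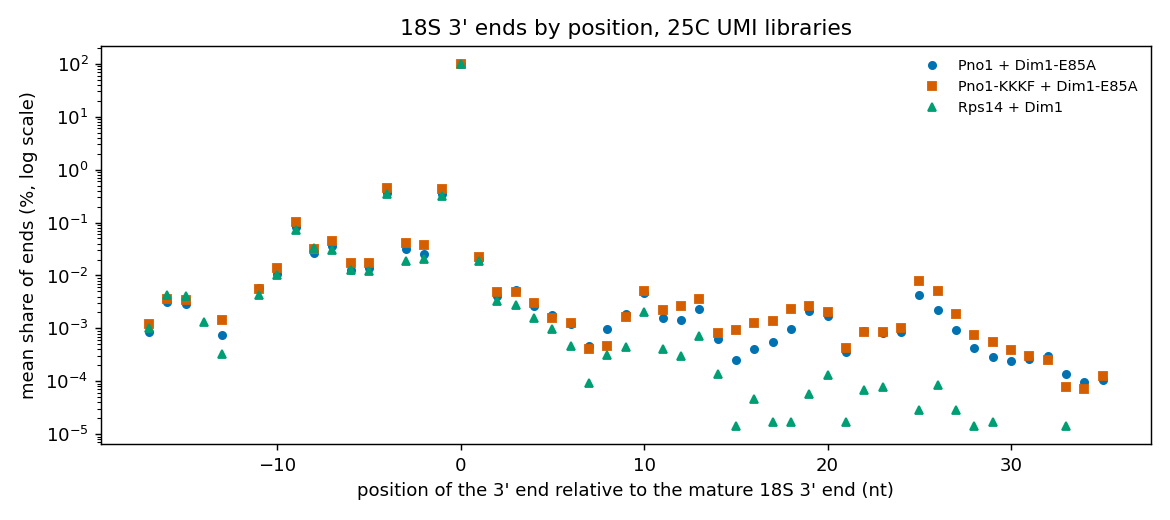
Mean share of 18S 3' ends by position, in percent on a log axis, against the position relative to the mature 3' end in nt, for the 25 °C UMI libraries of the 3 strains (n = 3, 3 and 2). Positions with no ends are not drawn. The strains lie close together upstream of 0. Rps14 + Dim1 lies below Pno1 from +3 on, and lowest of the strains beyond about +10.

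The library protocols were compared within strain. At 25 °C, miscleaved odds were 2.13-fold lower in UMI libraries than in universal-linker libraries of the same strain (log2 difference -1.09, SE 0.27, exact permutation p = 0.01, adjusted p = 0.02 over 6 tests). That p is the smallest that 100 arrangements allow. The linker and the purification changed together, and reads began at about -40 in universal-linker libraries and -61 in UMI libraries. UMI and universal-linker libraries were also separate replicates. None of these differences can be told apart. Between 30 °C and 25 °C with the universal linker, miscleaved odds differed by -0.21 on the log2 scale (SE 0.30, exact permutation p = 0.52). Without Pno1-KKKF replicate 4 this was -0.50 (exact permutation p = 0.075), and without Pno1-KKKF replicate 5 it was -0.047 (exact permutation p = 0.95). Extended odds were 2.28-fold lower at 25 °C (log2 difference -1.19, SE 0.43, exact permutation p = 0.01, adjusted p = 0.02), again at the smallest possible p. The 30 °C libraries include Pno1 replicate 1, whose extended share of 0.422% was above all others of its strain. The temperatures were run in separate sets of replicates, so temperature cannot be told apart from a difference in preparation.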

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

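The tests of skipped nucleotides and of the difference between protocols were chosen only after the results they bear on had been seen. Of 16 checks for a library far from the other 7 of its group, over 8 pairs of group and measure, 2 passed the critical value, and chance passes about 1 in 20 groups. The extended share of Pno1 replicate 1 was 0.422%, above all others of its strain. The depth of Pno1-KKKF replicate 5 was 4373681 reads, the deepest of its strain. These groups span 3 protocols, which widens them.

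At single far extended positions of 18S, the effect of Pno1-KKKF differed between protocols, and for the extended share as a whole it was -0.0029 on the log2 scale at 30 °C and 0.32 in the UMI libraries, a difference in the same direction that did not pass (exact permutation p = 0.53, adjusted p = 0.995). In an edgeR test of the difference, 15 of 47 positions between +13 and +29 had a higher effect in UMI libraries at 25 °C than in universal-linker libraries at 30 °C, and at 14 of them the effect was below 0 at 30 °C and above 0 in the UMI libraries. At +26 the log2 effect was -1.60 at 30 °C and 1.23 in the UMI libraries (edgeR adjusted p of the difference 0.000542). A single unusual library, Pno1 replicate 1, was weighed first: without it, 16 positions had a called difference (13 higher in the UMI libraries and 3 lower) and 13 of the 16 were shared with the full set, which argues against that library as the source. Temperature, linker, purification and the start of the reads change together between these protocols, which also used separate replicates. The 25 °C universal-linker libraries share linker and purification with 30 °C and were not in the edgeR test. In them, ends at +11 to +50 made up 0.00927% ± 9.75e-05 in Pno1 and 0.0105% ± 0.000928 in Pno1-KKKF (SD, n = 2 each). At 30 °C the shares were 0.0558% ± 0.00884 and 0.0251% ± 0.00483 (SD, n = 3 each). In UMI libraries they were 0.0246% and 0.0408% (means, n = 3 each). The lower share in Pno1-KKKF at 30 °C was thus absent at 25 °C with the same linker. A strain effect that depends on temperature and a difference in preparation stay open, as does a further part of linker or purification.

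Reads of the UMI libraries skipped 18S nucleotides 1778 and 1779, next to nucleotides 1781 and 1782, the adenosines that Dim1 dimethylates. Nucleotide 1781 itself was skipped less often, in 1.74% ± 0.0250 of reads in Rps14 + Dim1 (SD, n = 2). In Pno1 it was skipped in 0.155% ± 0.108 and in Pno1-KKKF in 0.143% ± 0.0164 (SD, n = 3 each). At nucleotide 1779 the skips were in 10.9% ± 1.09 of reads in Rps14 + Dim1 (SD, n = 2), 0.995% ± 0.559 in Pno1 and 1.00% ± 0.160 in Pno1-KKKF (SD, n = 3 each), and in universal-linker libraries in at most 0.00105%. Reads began at about -40 in universal-linker libraries and -61 in UMI libraries, and where the primer ends is not given. Whether nucleotide 1779 was read from rRNA in the universal-linker libraries is therefore not known. The ratio was 12.2-fold over Pno1 and 10.9-fold over Pno1-KKKF, each at an exact permutation p of 0.1, and 11.5-fold over both pooled at 0.0357, in each case the smallest possible. A candidate explanation is that reverse transcriptase skips near dimethylated adenosines, with a remainder of methylation in Dim1-E85A cells, but reads of Rps14 + Dim1 mixed into the other libraries could also leave such a remainder. The ratio of skips at nucleotide 1780 to those at 1779 was 0.141 to 0.167 in Rps14 + Dim1 and 0.170 to 0.259 in Dim1-E85A, with 0.170 too near the first range to decide.

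Depth above the floor of 3 reads also lay outside the amplified region. Its highest value was 62 reads in Pno1 replicate 1, 4 in Pno1 replicate 6, and 8, 8, 4, 13 and 22 in Pno1-KKKF replicates 1 to 5.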

How the results depend on the processing

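The rule for ends was changed after the depth profiles were seen, and the single-library runs of the protocol comparison were also chosen then. The higher truncated and miscleaved shares in Pno1-KKKF kept their direction throughout and lost their call under 7 of 12 alternatives each. Keeping negative drops in the sum, a choice also fixed at the start, gave 0.49 and 0.47 and kept the call. It yields the same truncated count as lasting drops by construction, so this result was fixed in advance and adds no support. The log2 differences (truncated, then miscleaved) were 0.29 and 0.28 with negative drops set to 0, the rule fixed at the start, 0.54 and 0.52 with ends within 1 nt taken as correct, and 0.49 and 0.47 with labels exchanged over all 16 libraries (adjusted p = 0.328, exact permutation). On the linear scale they were 0.70 and 0.71 percentage points. By protocol they were 0.35 and 0.32 (30 °C universal), 0.92 and 0.89 (25 °C universal) and 0.35 and 0.35 (UMI), where too few libraries end any call. Without single libraries they ranged from 0.34 to 0.59 and from 0.32 to 0.57. The extended share was reversed at 30 °C, at -0.0029, and ranged from 0.04 to 0.33 without single libraries. Apart from the number of libraries, the cause was not tested.

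Whether same-numbered libraries belong together was checked by correlating their deviations. From group means, which hold the protocols, correlations ran from -0.03 to 0.91, over 0.1 in 7 of 8, and 5 of 8 matched best with their own number. From means of group and protocol they ran from -0.51 to 0.73, over 0.1 in 5 of 8, and 3 of 8 matched best with their own number. Pairing was therefore not used in the main tests, and the counts of pairs given above are descriptive only. With the replicate block, the sign-flip test gave 0.49 for truncated ends (exact adjusted p = 0.0469), and edgeR called 0 positions.

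Against Rps14 + Dim1, the log2 difference from Pno1 reversed to 2.46, and that from Pno1-KKKF to 2.28, with negative drops set to 0, which counts skips as ends. Without single libraries these ranged from -0.37 to 0.021 and from -0.66 to -0.32. The 25S difference ranged from -0.18 to 0.040, the difference of 18S and 25S effects from 0.17 to 0.67, and the protocol differences from -0.50 to -0.05 and from -1.26 to -0.80.

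Called 18S positions in Pno1-KKKF were 0 in the 16 runs without a library, 1 with DESeq2's default size factors, 1 with negative drops set to 0 (-20), and 10, 2 and 6 in the 30 °C universal, 25 °C universal and UMI protocols alone. Against Rps14 + Dim1 they were 16 with TMM, 40 with negative drops set to 0 and 15 to 26 without single libraries. Position 0 there reversed to -0.13 with negative drops set to 0. Thinning to equal depth left the truncated difference at 0.49. Folds at the far extended positions rest on small counts, since Rps14 + Dim1 libraries held few or no ends there. Their depth was like that of the Pno1 UMI libraries, with 2943984 and 3518259 ends against 3088186 to 3466530.

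Values of single positions changed sign in 63 cases, 60 of them past no threshold. Scaling shifts all positions together. Against Rps14 + Dim1 it took position 0 to 0.60 (TMM) and 0.65 (DESeq2's default), and -10, -2, -1, +1 and +2 to 0.38, 0.29, 0.46, 0.49 and 0.22 and to 0.64, 0.37, 0.52, 0.54 and 0.35. None of these lay above position 0. For Pno1-KKKF on 18S, TMM took position 0 to -0.40 and -3, -1, +1, +2, +4, +5 and +10 to -0.12, -0.20, -0.34, -0.073, -0.061, -0.26 and -0.38, none below position 0. On 25S, TMM took position 0 to 0.095 and -2, -1 and +1 to 0.072, 0.0096 and 0.036, and DESeq2's default took position 0 to 0.17 and these to 0.15, 0.081 and 0.11.

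The other sign changes for Pno1-KKKF on 18S were small. Position +1 had -0.0036 with DESeq2's default, -0.012 without the protocol term, and -0.057 and -0.019 with the universal linker at 30 °C and 25 °C. Position +10 had -0.020 with DESeq2's default, and -0.039 and -0.050 with the universal linker at 30 °C and 25 °C. Position +5 had -0.048 at 30 °C and -0.15 in UMI libraries, and -1 had -0.081 at 25 °C with the universal linker. Without single libraries, +1 ranged from -0.069 to 0.16, +3 from -0.37 to 0.070, +5 from -0.23 to 0.43 and +10 from -0.068 to 0.14. On 25S, -2 ranged from -0.32 to 0.25, -1 from -0.22 to 0.051, 0 from -0.0013 to 0.0059, +3 from -0.13 to 0.79 and +4 from -0.54 to 0.081. Against Rps14 + Dim1, -10 ranged from -1.33 to 0.62.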

Other observations

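The tests in this part were chosen after the values had been seen, except the count of splits and the run without Pno1-KKKF replicate 4, which was fixed at the start with the other single-library runs and picked out as a test of that library afterwards. In universal-linker libraries, reads skipped 18S nucleotide 1781 more often in Pno1-KKKF than in Pno1, and here too where the primer ends is not given. At 30 °C the skips were in 0.0145% ± 0.000835 against 0.00586% ± 8.12e-06 of reads (SD, n = 3 each), and at 25 °C in 0.00923% ± 0.000786 against 0.00455% ± 0.000955 (SD, n = 2 each). The ratio was 2.30-fold with an exact permutation p of 0.0167, the smallest that 120 arrangements allow. In UMI libraries the same nucleotide was skipped in 0.143% ± 0.0164 of reads in Pno1-KKKF and 0.155% ± 0.108 in Pno1 (SD, n = 3 each), with a ratio of 1.07 between means on the log scale and an exact permutation p of 0.8. The Rps14 + Dim1 UMI libraries skipped it in 1.74% ± 0.0250 of reads (SD, n = 2). With negative drops set to 0, the skip of nucleotide 1781 appears as a called end at -20 between Pno1-KKKF and Pno1.

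The UMI libraries also held ends beyond +50, at 0.00991% ± 0.00248 in Pno1, 0.00895% ± 0.00299 in Pno1-KKKF (SD, n = 3 each) and 0.00216% ± 0.000206 in Rps14 + Dim1 (SD, n = 2). Of these, +72 to +75 held 185 to 267 ends per library in Pno1, 118 to 213 in Pno1-KKKF, and 55 and 54 in Rps14 + Dim1. Whether these ends are set by the length of the reads is not known from the labels, so their number, and the total beyond +50 that holds them, are not read as a measure of extended rRNA. In the A2 region, Rps14 + Dim1 replicates 1 and 2 held 6 and 0 ends.

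The higher truncated share in Pno1-KKKF was weighed against breakage or trimming of all rRNA, which could raise the 25S share alike. The 18S effect on truncated ends exceeded the 25S effect by 0.43 on the log2 scale (exact permutation p = 0.25), which leaves that explanation open. The higher truncated 18S share was also weighed against a single library. Without Pno1-KKKF replicate 4 the strain difference was 0.34 (adjusted exact permutation p = 0.0912), smaller and no longer called, so its size rests in part on that library. A loss of accuracy in cleavage remains a hypothesis beside both. For single positions, edgeR called 0 in the real split and at most 4 in the other splits, and with a real count of 0 all 100 of 100 within-protocol splits give as many, which tests nothing. At an unadjusted p under 0.05 edgeR gave 6 positions in the real split, and 20 of 100 splits gave as many, so chance is not excluded for these.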
